A study of Mus musculus with 9 samples.

How the data were processed

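Gene expression was measured in the lumbar spinal cord of 9 mice in 3 groups of 3, each mouse on an Affymetrix mouse oligonucleotide array of its own. Per the labels, total RNA was reverse-transcribed with an oligo-dT primer, amplified by in vitro transcription with biotinylated nucleotides and hybridised, and the arrays were scanned and summarised with MicroArray Suite 5.0 under default statistical and scaling settings. The deposited intensity values hold 1 signal per probe set on a linear scale, and the authors scaled each array to a common level. The labels state a target intensity of 1000, whereas the mean signal of every array, after leaving out the lowest and the highest 2%, was about 200 (200.062 to 200.067 over the 9 arrays). The arrays thus share 1 level of this mean, on a scale other than the labels state. An equal mean does not settle the differences between arrays, and other scalings were run as alternatives. Detection calls, scanner images and a genome build were not used here.

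Groups were taken from the sample titles, and the replicate numbers only name the mice. The labels give each array to a separate mouse, so the spread between arrays holds the difference between animals. Precision is limited by the number of arrays. Signals were taken to log2, with the 6 values at 0 set to the smallest positive value, 0.1. The 64 control probe sets were left out of all tests, and of the 22690 probe sets the 14405 with a signal of at least 51.4, the 40th percentile of all values, in at least 3 arrays were kept. Of all probe sets 20393 had 1 gene symbol, 691 had several and 1555, controls aside, had none. Symbols came from the platform annotation and were brought up to date for 20364 probe sets through their Entrez number in the RefSeq gene table of GRCm38.p6. No gene was named from a probe set with several symbols. A gene was represented by the kept probe set with the highest mean log2 signal, which gave 8639 genes.

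A linear model with a mean for each of the 3 groups was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05. Adjusted p-values of genes are those of their probe sets in this fit. SE denotes the moderated standard error of the log2 difference. Differences among the 3 groups together were tested with the moderated F test. The 3 comparisons were nmd vehicle with wild-type vehicle, nmd transplanted with nmd vehicle, and nmd transplanted with wild-type vehicle.

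Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They cover cell types (motor neuron, pan-neuronal, interneuron, astrocyte, microglia, oligodendrocyte and myelin, oligodendrocyte precursor, neural stem and progenitor, endothelial, meningeal fibroblast, ependymal, Schwann cell, dorsal root ganglion neuron, skeletal muscle, adipocyte, erythroid, neutrophil, lymphocyte) and pathways (axon injury, p53, reactive astrocyte, disease-associated microglia, interferon, MHC class I and complement, cholesterol biosynthesis, cell cycle, neurotrophic factors, unfolded protein response, heat shock, glucocorticoid and fasting response, circadian clock, immediate early genes, ribosomal proteins, tRNA synthetases, RNA helicase and survival motor neuron complex, oxidative phosphorylation, glutamate and ion channels, Hox genes, aldehyde dehydrogenases). Of these 39 lists the 34 with at least 4 measured genes were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The same test with a correlation estimated from the data, and fry, were run as alternatives. A call can be lost under the estimated setting without a higher correlation, so such a loss is not read as an effect of correlation. Xist and Y-linked genes were fixed as markers of sex.

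Genes are named by this rule: Ighmbp2 in every comparison; for each comparison the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose 3 arrays of either group all lay above the 3 of the other; and up to 4 members of each list with the lowest p, other members past the threshold being given as counts. Not every gene the rule selects is given: the text prints 7 of the 8 largest rises in nmd against wild-type vehicle, and lists that did not pass camera are given mainly as counts. Any other gene is said to have been chosen after its values were seen. How far the transplanted arrays moved along the difference between nmd and wild type was measured by cross-fitting: for each nmd vehicle array in turn, the 200 genes highest and the 200 lowest in the other nmd vehicle arrays against wild type were taken, and the move from the array left aside to the transplanted mean was divided by its distance from the wild-type mean, so that a negative ratio is a move toward wild type.

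The scripts were tested on simulated data with the spread of these arrays, 14405 probe sets of which 200 were changed, over 10 runs. For nmd vehicle with wild type, 78.6% of changes of 1 log2 unit and 98.6% of changes of 2 were recovered in the right direction, with 5.63% false among the calls. For transplanted with nmd vehicle these shares were 82.3%, 98.0% and 5.54%, and for transplanted with wild type 78.7%, 97.5% and 4.61%. With no effect of transplantation the cross-fitted ratio averaged -0.0072 (SD 0.017 over 20 runs), against -0.199 without cross-fitting. The simulated genes varied independently of each other. This SD therefore leaves out correlation between genes and is no measure of the spread of the ratio in the real arrays.

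The alternatives were no filter and a stricter filter at a signal of 128.5, quantile normalization, median centring, a pseudocount of 64, no intensity trend, a robust variance prior, array weights, the replicate number as a block, fits of only the 2 groups compared, each array left out in turn, the mean of all probe sets of a gene in list tests, and fewer or more genes in each direction for the cross-fitted ratio. A fit with Xist as a covariate and a fit without the pair of arrays low in Xist were added after seeing the data.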

Results

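The nmd mouse carries a mutation in Ighmbp2, the gene of an RNA and DNA helicase, and is a model of spinal muscular atrophy with respiratory distress (SMARD1), in which motor neurons degenerate. Neural stem cells isolated from spinal cord for high aldehyde dehydrogenase activity and low side scatter were injected intrathecally into nmd mice on postnatal day 1. Nmd and wild-type mice given vehicle by the same procedure were the controls, and the lumbar spinal cord was taken from all at 6 weeks of age, 3 mice per group, all labelled male. The median signal of an array lay between 73.6 and 83.5. Arrays of a group were alike, with a mean correlation of log2 signals of 0.966 within wild-type vehicle, 0.972 within nmd vehicle and 0.963 within nmd transplanted. The mean was 0.960 between wild-type and nmd vehicle arrays, 0.936 between nmd vehicle and transplanted arrays, and 0.918 between wild-type and transplanted arrays. The leading principal component held 43.9% of the variance and placed the groups at -26.3 ± 2.55 (wild-type vehicle), -11.4 ± 1.62 (nmd vehicle) and 37.7 ± 9.34 (nmd transplanted; SD, n = 3 each). Across the 3 groups together 3676 of 14405 probe sets differed by limma's F test.

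The control probe sets for 18S ribosomal RNA set the transplanted arrays apart from the others. The signal of the 3' probe set was 3821 ± 372 in wild-type vehicle, 2936 ± 885 in nmd vehicle and 153 ± 25.3 in transplanted arrays (SD, n = 3 each), 18.8-fold lower in the transplanted arrays than in nmd vehicle and 25.2-fold lower than in wild type. The 5' probe set was 23.2-fold and 26.7-fold lower and the middle one 5.66-fold and 5.67-fold lower. The ratios of 3' to 5' signal, a measure of RNA integrity, were 1.26 ± 0.067, 1.11 ± 0.044 and 1.15 ± 0.055 for beta-actin and 0.769 ± 0.040, 0.809 ± 0.032 and 0.846 ± 0.018 for GAPDH in the same order. For beta-actin the 3 wild-type arrays (1.21 to 1.34) lay above all 6 nmd arrays (1.07 to 1.19), and for GAPDH the 3 transplanted arrays (0.826 to 0.860) lay above the 3 wild-type arrays (0.742 to 0.815). Xist, the X-inactivation transcript of female cells, read 69.4, 418 and 519 in the wild-type vehicle arrays, 58.5, 794 and 309 in the nmd vehicle arrays and 449, 403 and 316 in the transplanted arrays, although all mice are labelled male.

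**Figure D1:**
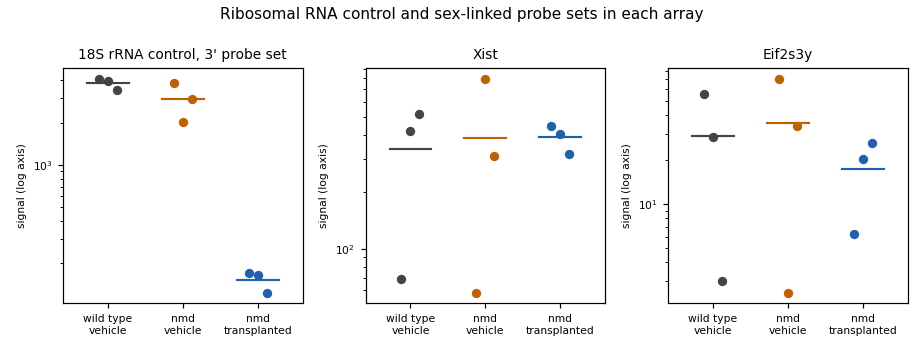
Signal of the 18S ribosomal RNA 3' control probe set, Xist and Eif2s3y in each of the 9 arrays, on log axes. Points are arrays and lines are group means. The 18S signal lay between 124 and 171 in the transplanted arrays and between 2038 and 4102 in the other 6, and Xist was low in 2 arrays, wild-type vehicle replicate 1 and nmd vehicle replicate 1.

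Ighmbp2, the mutated gene, was measured by 3 probe sets, all dim and below the limit for testing. For the brightest the signal was 34.2 ± 3.65 in wild-type vehicle, 29.1 ± 0.416 in nmd vehicle and 29.3 ± 5.05 in transplanted arrays (SD, n = 3 each). In a limma fit without the filter it differed between nmd and wild-type vehicle by -0.23 on the log2 scale (SE 0.28, adjusted p = 0.789), and between transplanted and nmd vehicle by -0.0069 (SE 0.28, adjusted p = 0.993). The lowest adjusted p of the 3 for nmd against wild type was that of the dimmest, at -1.42 (SE 0.52, adjusted p = 0.303) from signals of 6.13 ± 1.62 and 2.30 ± 0.624. The position of these probes relative to the mutation was not determined, so they do not check the genotype labels. Of the 20 measured genes next to Ighmbp2 in the gene order of GRCm38.p6, all on the same side, 0 passed limma's threshold between nmd and wild-type vehicle, and 3 (15.0%) had an unadjusted p under 0.05, against 15.7% of all genes.

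The comparison of nmd with wild-type vehicle asks what the mutation changes in the lumbar cord at 6 weeks. Igf1, insulin-like growth factor 1, went from 46.9 ± 10.9 to 112 ± 18.9 (2.41-fold, adjusted p = 0.0307). Fabp7, a fatty acid binding protein of radial glia, rose by 0.98 on the log2 scale (SE 0.18), and Slc1a3, the glial glutamate transporter GLAST, by 1.14 (SE 0.17, adjusted p = 0.0232). Pvalb, the calcium-binding protein of fast-firing interneurons and of proprioceptive afferents, fell by 1.17 (SE 0.17, adjusted p = 0.021), while the neuropeptide gene Npy rose by 0.65 (SE 0.11, adjusted p = 0.034). Of the 13 measured genes of the motor neuron list, 0 passed limma's threshold, over all genes or adjusted over the list alone. The closest was Isl1, a transcription factor of motor and sensory neurons, at 1.55 (SE 0.53, adjusted p = 0.20), from signals of 9.83 and 24.4, both under the limit of 51.4 used for the filter.

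In all, 85 probe sets passed limma's threshold, 50 higher and 35 lower in nmd, and 2224 had an unadjusted p under 0.05. The separate fit to genes called 42 genes higher and 28 lower. Among the largest rises were those of Rfc3, a subunit of the clamp loader of DNA replication (2.57 on the log2 scale, SE 0.44), Mfap2, a microfibril protein (2.02, SE 0.39), and Fxyd6, a regulator of the sodium pump (1.32, SE 0.22). Igf1 followed at 1.27, then Crabp1, a retinoic acid binding protein (1.18, SE 0.23), Slc1a3, and Pclaf, a partner of the replication clamp (1.08, SE 0.17). The largest falls were those of Cap1, a regulator of actin (-2.35, SE 0.34), Adgrv1, an adhesion receptor (-2.33, SE 0.40), Wdfy1 (-1.68, SE 0.29), and Tnfaip6, a hyaluronan-binding protein (-1.65, SE 0.28). These were followed by Tmod1, which caps actin filaments (-1.43, SE 0.25), Hsf4, a heat shock factor (-1.35, SE 0.26), Efhd1 (-1.29, SE 0.24) and Pde8a, a cAMP phosphodiesterase (-1.25, SE 0.20). By the rule for naming genes, all 3 arrays of nmd vehicle lay beyond all 3 of wild type for each. Over all genes the groups lay apart in this way for 23.1%, against 10% by chance. Rfc3 had mean signals under the limit of 51.4 in both groups (5.77 and 34.6). Mfap2 (31.7) and Igf1 in wild type, and Adgrv1 (12.7), Tnfaip6 (36.4) and Hsf4 (32.5) in nmd vehicle, had them in 1 group, where the fold depends on the background.

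In nmd against wild-type vehicle, 14 of the 15 measured cell cycle genes had a positive log2 difference with a median of 0.37. Over all genes 0 passed limma's threshold, and 6 rose when adjusted over the list alone. Mcm6 differed by 1.63 (SE 0.38, adjusted p = 0.070), Top2a by 0.84 (SE 0.20, adjusted p = 0.083), Mcm2 by 1.28 (SE 0.32) and Rrm2 by 1.00 (SE 0.27), with Mcm6 and Mcm2 under 51.4 in wild type. The list passed camera with adjusted p = 4.2e-05, and it was lost at adjusted p = 0.543 with an estimated correlation, the alternatives spanning 1.83e-06 to 0.543. Of 12 neural stem and progenitor genes, Fabp7 rose and 0 fell (3 rose and 0 fell adjusted over the list alone), with Sox4 at 0.67 (SE 0.14, adjusted p = 0.056) and Sox2 at 0.40 (SE 0.12, adjusted p = 0.14). The list passed with adjusted p = 0.0397, but adjusted p = 0.543 with an estimated correlation, over a range of 0.0136 to 0.543. Of 15 oligodendrocyte and myelin genes, 14 had a negative difference with a median of -0.25. Over all genes 0 passed limma's threshold, and 5 fell adjusted over the list alone. Aspa differed by -0.84 (SE 0.18, adjusted p = 0.060), Mobp by -0.56 (SE 0.12, adjusted p = 0.065), Fa2h by -0.58 (SE 0.14) and Mal by -0.64 (SE 0.16). This list passed with adjusted p = 1.74e-04, but adjusted p = 0.543 with an estimated correlation, over a range of 7.02e-06 to 0.543. With the strict filter the cell cycle (adjusted p = 0.121) and progenitor lists (adjusted p = 0.0635) lost their calls, so that 0 lists were higher, and fry lost all 3 (adjusted p = 0.101, 0.268 and 0.268). The progenitor list was also lost with the mean of all probe sets of a gene (adjusted p = 0.0982) and without the pair of arrays low in Xist (0.0823). The beta-actin ratio of 3' to 5' signal also set these groups apart, at 1.21 to 1.34 in wild-type and 1.07 to 1.16 in nmd vehicle arrays.

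The microglia list passed camera as lower (adjusted p = 0.0397, but adjusted p = 0.564 with an estimated correlation; range 0.0163 to 0.564). Of its 15 genes 0 passed limma's threshold over all genes and 2 fell adjusted over the list alone, with Tyrobp at -0.55 (SE 0.15, adjusted p = 0.13) and C1qb at -0.58 (SE 0.17, adjusted p = 0.15). The neutrophil list was lower with adjusted p = 0.0458, but adjusted p = 0.543 with an estimated correlation (range 0.0054 to 0.543). Of its 6 genes 0 passed limma's threshold, over all genes or adjusted over the list alone, S100a9 standing at -0.82 (SE 0.31, adjusted p = 0.23) and S100a8 at -0.84 (SE 0.37, adjusted p = 0.31), both under 51.4 in nmd vehicle. The glucocorticoid and fasting list was lower with adjusted p = 0.0397, but adjusted p = 0.543 with an estimated correlation (range 0.0061 to 0.543). Of its 15 genes 0 passed limma's threshold over all genes and 1 fell adjusted over the list alone, with the metallothionein Mt1 at -0.81 (SE 0.21, adjusted p = 0.097) and Cdkn1a at -0.53 (SE 0.17, adjusted p = 0.18). Further alternatives ended these 3 calls. Microglia was lost with the strict filter (adjusted p = 0.0635), no filter (0.0995), array weights (0.0570), fry (0.305) and without the pair of arrays low in Xist (0.0823). Neutrophil was lost with no filter (adjusted p = 0.370), a pseudocount of 64 (0.0539), array weights (0.0617), fry (0.268) and without that pair (0.251), and glucocorticoid by fry (0.268) and without that pair (0.174). Ighm, the immunoglobulin heavy chain and the only gene measured of the lymphocyte list, fell by 1.10 (SE 0.17, adjusted p = 0.023).

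The remaining 28 lists tested did not pass camera, with adjusted p from 0.0549 to 0.999, among them motor neuron (0.769), pan-neuronal (0.136), interneuron (0.836), astrocyte (0.578), oligodendrocyte precursor (0.0549), axon injury (0.485), disease-associated microglia (0.116), interferon (0.825), cholesterol biosynthesis (0.0549), ribosomal protein (0.0657), heat shock (0.761), and RNA helicase and survival motor neuron complex (0.416). Igf1 was the gene that rose in the disease-associated microglia and neurotrophic factor lists, Npy that in the axon injury and interneuron lists, and Slc1a3 that in the astrocyte list, while Pvalb fell in the interneuron and skeletal muscle lists. For the motor neuron, interneuron, interferon, unfolded protein and Hox lists the median, the mean and the direction of camera differed in sign. The 85 calls depended on which arrays were used: limma made 0 without wild-type vehicle replicate 1 (1895 unadjusted) or without nmd vehicle replicate 2 (1707 unadjusted). It made 1 without nmd vehicle replicate 3, 7 without nmd vehicle replicate 1, 8 without wild-type vehicle replicate 3, 34 and 193 without transplanted replicates 2 and 3, and 254 without wild-type vehicle replicate 2. The count was also 15 with no filter, 41 after quantile normalization, 1 with no intensity trend and 371 with array weights, and the 6 lists became 3 without wild-type vehicle replicate 1. The cell cycle and myelin lists passed camera with any array left out. The microglia list did not without wild-type vehicle replicates 1 or 2, nmd vehicle replicates 1 or 2 or transplanted replicate 1 (adjusted p up to 0.144), nor the progenitor list without wild-type vehicle replicate 1, nmd vehicle replicates 2 or 3 or any transplanted array (up to 0.0946). The neutrophil list was lost without wild-type vehicle replicates 1 or 3, nmd vehicle replicates 1 or 3 or transplanted replicate 3 (up to 0.238), and the glucocorticoid list without wild-type vehicle replicate 1 (0.110).

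The comparison of transplanted with vehicle-treated nmd mice asks what the stem cell graft changes in the nmd cord. Some genes of young neurons, which had no list and were not tested as a group, were among those that rose. Dcx, doublecortin, a microtubule protein of migrating neuroblasts, went from 114 ± 24.3 to 920 ± 333 (7.86-fold, adjusted p = 1.54e-05). St8sia2, a polysialyltransferase that modifies neural cell adhesion molecule, rose from 63.9 ± 4.88 to 599 ± 179 (9.13-fold, adjusted p = 1.85e-06), and the growth cone gene Gap43 rose by 1.46 on the log2 scale (SE 0.17, adjusted p = 2.1e-04). Genes of glia were among those that fell, such as Gjb1, the connexin of oligodendrocytes (-1.37, SE 0.14), and Sox10, the transcription factor of the oligodendrocyte lineage (-1.44, SE 0.17). Aqp4, the water channel of astrocyte endfeet, fell as well (-1.05, SE 0.11), along with 13 of 19 genes of cholesterol synthesis. The motor neuron list did not pass camera (adjusted p = 0.837), with members from -0.62 to 1.85: of 13 genes, Isl1 rose by 1.85 (SE 0.53, adjusted p = 0.035) from a signal under 51.4, Ache, acetylcholinesterase, fell by 0.62 (SE 0.12, adjusted p = 0.005), and 11 did not pass. The 18S control differed 18.8-fold between the same arrays.

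The separate fit to genes called 778 genes higher and 809 lower in transplanted mice. Over probe sets 2479 passed limma's threshold, 1272 higher and 1207 lower, and 4446 had an unadjusted p under 0.05. The balance turned with the scaling, to 1139 higher and 1307 lower after quantile normalization and 1098 and 1371 under median centring. A change of more than 1 log2 unit was seen in 279 of those higher and 183 of those lower. The groups lay apart for 37.3% of genes, against 10% by chance. After St8sia2 (3.19, SE 0.19), the largest rises were those of Hcn3, a pacemaker channel (3.16, SE 0.33), Msantd2 (3.03, SE 0.79), Alas2, the heme synthesis enzyme of red cells (3.01, SE 0.33), and Dcx (2.97, SE 0.24). They continued with Ptgds, prostaglandin D synthase (2.77, SE 0.55), Cxadr, an adhesion molecule of developing neurons (2.74, SE 0.33), and Tent5c (2.66, SE 0.31). The largest falls were those of Grin2c, an NMDA receptor subunit (-2.20, SE 0.42), Col9a3, a collagen chain (-2.09, SE 0.40), Bmp4, a secreted signal that favours astrocyte fate (-2.04, SE 0.21), and Il23a (-2.02, SE 0.56). Further falls were those of the kinase Cdk18 (-1.93, SE 0.49), the neuropeptide Nmu (-1.83, SE 0.57), Hapln1, a link protein of perineuronal nets (-1.81, SE 0.56), and the protease Ctsk (-1.79, SE 0.41). Msantd2, Hcn3 and Tent5c in nmd vehicle, and Il23a, Nmu, Hapln1, Grin2c and Ctsk in transplanted arrays, had mean signals under 51.4, where the fold depends on the background.

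Of 12 neural stem and progenitor genes 5 rose and Prom1 fell (6 and 1 adjusted over the list alone). Beside Dcx these were Cd24a (1.91, SE 0.14, adjusted p = 9.6e-06), Sox4, a transcription factor of new neurons (1.15, SE 0.14), Fabp7 (1.26, SE 0.18) and 1 more. Prom1, a membrane protein used to sort neural stem cells, fell by 0.54 (SE 0.14, adjusted p = 0.018). The list passed camera with adjusted p = 8.11e-04, but adjusted p = 0.279 with an estimated correlation (range 2.89e-04 to 0.279). Neuronal genes moved in both directions: of 16 pan-neuronal genes 5 rose and 2 fell (5 and 4 adjusted over the list alone). The tubulin Tubb3 (0.91, SE 0.11), Map2 (0.91, SE 0.19) and Uchl1 (0.37, SE 0.09) rose, and Nefh, the heavy neurofilament of mature large axons, fell by 1.13 (SE 0.16, adjusted p = 6.2e-04). Camera gave adjusted p = 0.512. Of 16 axon injury genes 6 rose and Nts fell (7 and 2 adjusted over the list alone), led by Gap43, Npy (0.81, SE 0.11), Ngfr, the low-affinity neurotrophin receptor (2.42, SE 0.40), and Jun (0.53, SE 0.12). The axon injury list passed camera with adjusted p = 0.0334. The call ended at adjusted p = 0.279 with an estimated correlation (range 0.0021 to 0.279). Without nmd vehicle replicate 1 this list did not pass (adjusted p = 0.0620), nor without the pair of arrays low in Xist (0.0743). Ngfr had a mean signal under 51.4 in nmd vehicle. The 18S control differed 18.8-fold between the same arrays.

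**Figure D2:**
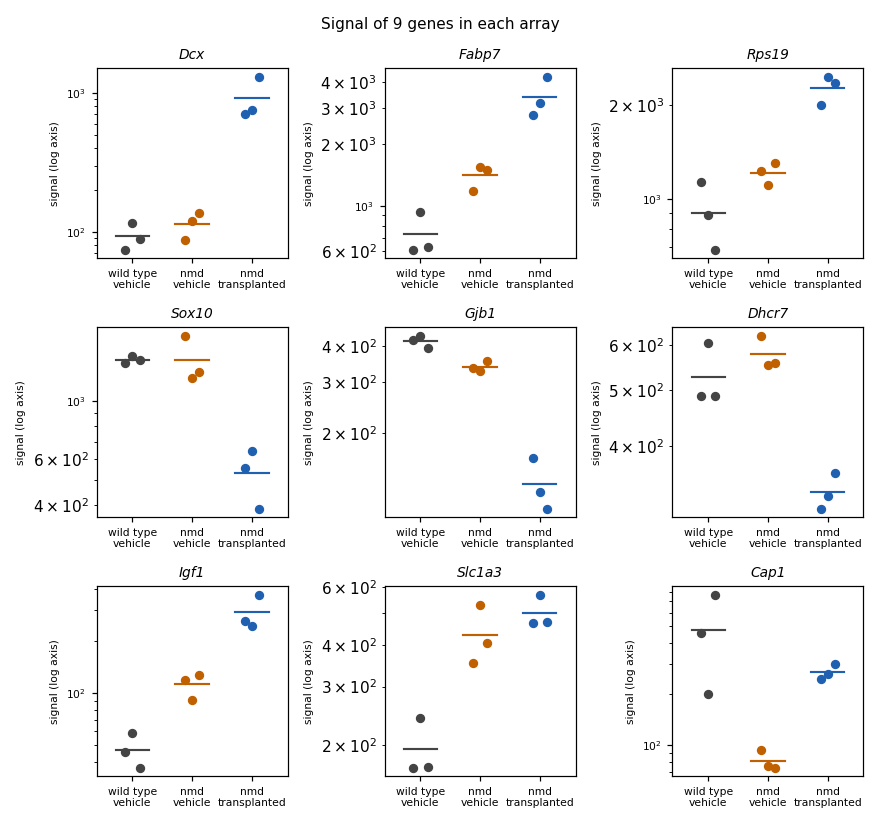
Signal of 9 genes in each array of the 3 groups, on log axes. Points are arrays and lines are group means. Dcx averaged 920 in the transplanted arrays against 114 in nmd vehicle and 92.8 in wild-type vehicle, while Igf1 averaged 46.9, 112 and 292 from wild-type vehicle through nmd vehicle to nmd transplanted.

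In transplanted against nmd vehicle arrays, 9 of 15 oligodendrocyte and myelin genes fell and 0 rose (10 and 1 adjusted over the list alone), with a median of -0.83. Beside Gjb1 and Sox10 these included Gal3st1, the sulfatide synthase (-1.34, SE 0.17), and Gamt (-0.94, SE 0.13). The list passed camera with adjusted p = 1.1e-05, but adjusted p = 0.290 with an estimated correlation (range 1.02e-07 to 0.290). Of 7 oligodendrocyte precursor genes 4 fell, over all genes and adjusted over the list alone: Olig2 (-1.10, SE 0.14), Olig1 (-0.48, SE 0.09), Nkx2-2 (-0.78, SE 0.15) and Pdgfra (-0.37, SE 0.12). The precursor list passed camera with adjusted p = 0.00396. This call was lost at adjusted p = 0.232 with an estimated correlation (range 7.71e-04 to 0.232). Of 12 astrocyte genes 4 fell (6 adjusted over the list alone): Mlc1 (-1.21, SE 0.13), Aqp4, S100b (-0.81, SE 0.18) and Atp1b2 (-0.52, SE 0.15). The astrocyte list passed camera with adjusted p = 0.00171. The list did not pass at adjusted p = 0.405 with an estimated correlation (range 2.94e-04 to 0.405). Of 19 cholesterol synthesis genes 13 fell (17 adjusted over the list alone) with a median of -0.58, led by Cyp51 (-0.79, SE 0.10), Dhcr7 (-0.80, SE 0.12), Ebp (-0.81, SE 0.12) and Sc5d (-0.74, SE 0.12), enzymes of the late steps. That list passed with adjusted p = 6.36e-09, but adjusted p = 0.232 with an estimated correlation (range 1.51e-11 to 0.232). Among 15 microglia genes P2ry12, a receptor of resting microglia, fell by 0.98 (SE 0.14, adjusted p = 5.9e-04) and Csf1r by 0.52 (SE 0.13, adjusted p = 0.018), also adjusted over the list alone, and camera gave adjusted p = 0.502. Of 10 endothelial genes 0 passed limma's threshold, over all genes or adjusted over the list alone, the closest being Flt1 at 0.49 (SE 0.21, adjusted p = 0.14). The 18S control was 18.8-fold lower in the arrays in which these glial and lipid genes were lower.

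In the same comparison 9 of 15 cytosolic ribosomal protein genes rose and 0 fell (11 and 0 adjusted over the list alone), among them Rps4x (0.52, SE 0.09), Rps19 (0.91, SE 0.16), Rps15 (0.54, SE 0.10) and Rplp0 (0.62, SE 0.11). The ribosomal protein list passed camera with adjusted p = 4.6e-06. It was lost at adjusted p = 0.279 with an estimated correlation (range 6.29e-08 to 0.279). Of 4 erythroid genes Alas2 and Slc4a1, the anion exchanger of red cells (2.03, SE 0.28), rose, and 3 rose adjusted over the list alone. The list passed with adjusted p = 0.0048, but adjusted p = 0.279 with an estimated correlation (range 0.0016 to 0.279). Of 9 interferon response genes 3 rose (5 adjusted over the list alone), Rsad2 (1.14, SE 0.24), Oas1a (1.68, SE 0.49) and Rtp4 (1.68, SE 0.52). The interferon list passed camera with adjusted p = 0.00382. The call ended at adjusted p = 0.458 with an estimated correlation (range 3.02e-05 to 0.458), and fry gave adjusted p = 0.0698. Slc4a1 and Rtp4 had mean signals under 51.4 in nmd vehicle. The remaining 25 lists tested did not pass camera, with adjusted p from 0.0707 to 0.960, including the aldehyde dehydrogenase list (0.232), of whose 9 genes Aldh1a1 fell by 0.87 (SE 0.21, adjusted p = 0.014; 1 rose and 5 fell adjusted over the list alone). Others were neurotrophic factors (0.249; Igf1 rose by 1.37, SE 0.21, and Ngfr), neutrophil (0.113; S100a9 rose by 1.27, SE 0.31, and S100a8 by 1.17, SE 0.37, both from signals under 51.4), heat shock (0.502) and Hox genes (0.114; Hoxc6 rose by 1.02, SE 0.20, and Hoxb5 by 1.49, SE 0.40). Over all genes, both directions were seen in p53 (4 rose and 2 fell of 14), reactive astrocyte (3 and 1 of 15), heat shock (3 and 1 of 13), oxidative phosphorylation (3 and 2 of 30), tRNA synthetases (2 and 1 of 22) and interneuron (2 and 1 of 14). So it was for glucocorticoid (1 and 2 of 15), immediate early (1 and 2 of 9), disease-associated microglia (1 and 1 of 14) and meningeal fibroblast (1 and 1 of 9). In the clock list 4 of 12 fell, in the glutamate and ion channel list 2 of 15 and in the unfolded protein list 2 of 20, while 1 of 15 rose in the cell cycle list and 1 of 8 in MHC class I and complement. Of the 11 measured Hox genes, a list fixed for spinal segments, 8 had a positive difference, with a median of 0.72. Adjusted over the list alone 4 of them rose and 0 fell. Whether the segments taken differed between the groups was not tested. For the motor neuron and endothelial lists the median, the mean and the direction of camera differed in sign. The count of 2479 probe sets dropped to 1643 without nmd vehicle replicate 1, to 1577 without nmd vehicle replicate 2, and to 1613 without the pair of arrays low in Xist. The 18S control differed 18.8-fold between the same arrays.

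Whether the transplanted arrays moved toward wild type was measured on genes chosen from nmd vehicle arrays other than the one compared. The cross-fitted ratio was 0.247 on average, with 0.40, 0.195 and 0.145 for the 3 nmd vehicle arrays in turn, all positive and so away from wild type. Among the 42 genes higher in nmd than in wild-type vehicle, 21 were also higher in transplanted than in nmd vehicle arrays (3.78 for independent lists, 0.04 in simulated unchanged groups) and 8 were lower (3.93 for independent lists, 23.1 simulated). Among the 28 lower in nmd, 4 were higher in transplanted arrays (2.52 for independent lists, 16.4 simulated), namely Adgrv1 (2.13), Cap1 (1.73), Hsf4 (1.13) and Wdfy1 (1.01 on the log2 scale), and 3 were lower (2.62 for independent lists, 0.01 simulated), namely Anln, Ighm and St6galnac3. The 8 that rose in nmd and fell after transplantation were Cemip2, Dnmt3a, Fxyd7, Gp1bb, Kif22, Mgll, Peli1 and Rims2. Anln, St6galnac3 and these 8 were chosen after their values were seen. Across genes, which are not independent replicates, the log2 differences of the pair of comparisons correlated at r = -0.048, against -0.50 in simulated unchanged groups sharing the nmd vehicle arrays. It turned to 0.063 with the strict filter and 0.017 with a pseudocount of 64, and was -0.282 with no filter. The covariance was -0.0065 against -0.020 simulated, a difference of 0.0135. The simulated overlaps, of as many top genes, were added after the observed ones were seen. The 3 nmd vehicle arrays were too few to split for the overlaps. They enter the pair of comparisons with opposite signs, so part of the overlaps in opposite directions and of the correlation may come from them. The 21 genes higher in both and the 3 lower in both stood against 0.04 (SD 0.20) and 0.01 (SD 0.1) simulated. For these same-direction overlaps the values argue against the shared arrays as their source. With the 18S difference the transplanted group cannot be told apart from its preparation.

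The comparison of transplanted nmd with wild-type mice asks how far the treated cord stands from the healthy one. The distance was larger than that of untreated nmd mice in number of genes, with 1247 higher and 1224 lower in the separate fit to genes. Over probe sets 3956 passed limma's threshold, 2140 higher and 1816 lower, and 5652 had an unadjusted p under 0.05. This balance turned with the scaling, to 2004 higher and 2056 lower after quantile normalization and 1790 and 2287 under median centring. Dcx rose 9.68-fold over wild type (SE 0.24 on the log2 scale, adjusted p = 4.5e-06), Igf1 by 2.64 on the log2 scale (SE 0.21, adjusted p = 7.6e-06) and Fabp7 by 2.23 (SE 0.18, adjusted p = 8.2e-06), and Gjb1 fell by 1.66 (SE 0.14) and Nefh by 1.36 (SE 0.16). Of 13 motor neuron genes Isl1 rose by 3.39 (SE 0.53, adjusted p = 7.03e-04) and Ache fell by 0.57 (SE 0.12, adjusted p = 0.0052), also adjusted over the list alone. The 18S control was 25.2-fold lower in these transplanted arrays than in wild type.

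The largest rises were those of Fads3, a fatty acid desaturase family member (3.89, SE 0.54), Rfc3 (3.63, SE 0.44), Mfap2 (3.48, SE 0.39), Bcl11b, a transcription factor of projection neurons (3.43, SE 0.68), Isl1, Hcn3 (3.32, SE 0.33), the nuclear pore gene Nup188 (3.28, SE 0.63) and Dcx (3.27). The largest falls were those of Grin2c (-2.63, SE 0.42), Nkx2-6 (-2.50, SE 0.64) and Cdk18 (-2.10, SE 0.49). Next were Grin2b, an NMDA receptor subunit (-2.07, SE 0.53), Msgn1 (-2.05, SE 0.37), Ccrl2 (-2.0, SE 0.42), Rab7b (-1.92, SE 0.15) and Ighm (-1.71, SE 0.17). All of those that rose except Dcx had mean signals under 51.4 in wild type, and all of those that fell except Cdk18, Rab7b and Ighm had them in transplanted arrays, where the fold depends on the background. The groups lay apart for 41.1% of genes, against 10% by chance. Of the 42 genes higher in nmd than in wild-type vehicle 35 were also higher here (6.06 for independent lists, 28.1 in simulated unchanged groups that share the wild-type arrays), and of the 28 lower 24 were also lower (3.97 for independent lists, 19.1 simulated). The log2 differences of both comparisons with wild type correlated across genes at r = 0.538, against 0.50 in simulated unchanged groups that share the wild-type arrays, and the covariance exceeded the simulated one by 0.067. The shared wild-type arrays were too few to split, so part of these overlaps may come from them. The 18S control differed 25.2-fold between the same arrays.

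Of 15 myelin genes 12 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -1.05, led by Gjb1, Fa2h (-1.41, SE 0.14), Sox10 (-1.47, SE 0.17) and Gamt (-1.08, SE 0.13). The myelin list passed camera with adjusted p = 9.32e-09. This call was lost at adjusted p = 0.308 with an estimated correlation (range 1.73e-10 to 0.308). Of 12 astrocyte genes 7 fell and 1 rose, over all genes and adjusted over the list alone, with Mlc1 at -1.39 (SE 0.13), Aqp4 at -0.81 (SE 0.11) and S100b at -1.0 (SE 0.18), while Slc1a3, which young astrocytes and radial glia also express, rose by 1.38 (SE 0.17). The list passed with adjusted p = 0.00241, but adjusted p = 0.432 with an estimated correlation (range 6.16e-04 to 0.432). Of 15 microglia genes 3 fell, P2ry12 (-1.01, SE 0.14), Csf1r (-0.78, SE 0.13) and Adgre1 (-0.48, SE 0.16), also adjusted over the list alone. The microglia list passed camera with adjusted p = 0.035. The list did not pass at adjusted p = 0.562 with an estimated correlation (range 0.0019 to 0.562). Of 19 cholesterol synthesis genes 10 fell, over all genes and adjusted over the list alone, led by Cyp51 (-0.71, SE 0.10) and Sc5d (-0.78, SE 0.12). The cholesterol list passed camera with adjusted p = 1.23e-04. It was lost at adjusted p = 0.348 with an estimated correlation (range 1.06e-05 to 0.348). Of 15 glutamate receptor and ion channel genes 8 fell and 2 rose, over all genes and adjusted over the list alone. Kcnj10, the potassium channel of glia (-1.12, SE 0.20), Slc1a1 (-0.57, SE 0.12) and Kcna2, a channel of mature axons (-1.14, SE 0.26), fell and the sodium channel Scn2a rose by 0.75 (SE 0.14). The channel list passed camera with adjusted p = 0.035. The call ended at adjusted p = 0.454 with an estimated correlation (range 0.0056 to 0.454). Of 12 circadian clock genes 5 fell, over all genes and adjusted over the list alone, led by the output genes Tef (-0.96, SE 0.14) and Dbp (-0.85, SE 0.16). The clock list passed camera with adjusted p = 0.0193. This call was lost at adjusted p = 0.454 with an estimated correlation (range 0.0056 to 0.454). Left-out arrays ended some of these calls: microglia without wild-type vehicle replicate 2 (adjusted p = 0.0776) or transplanted replicate 3 (0.221), glutamate and ion channels without wild-type vehicle replicate 2 (0.0550) or transplanted replicate 2 (0.109), and the clock without wild-type vehicle replicate 1 (0.0844). Microglia was also lost with the strict filter (adjusted p = 0.115), array weights (0.152), no filter (0.0555), fry (0.0780) and without the pair of arrays low in Xist (0.0517). The glutamate and ion channel list was lost with the strict filter (adjusted p = 0.0844), and the clock with no filter (0.0526) and without that pair (0.0897). The 18S control was 25.2-fold lower in the arrays in which these genes fell.

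Of 12 neural stem and progenitor genes 7 rose and Prom1 fell, over all genes and adjusted over the list alone, with Cd24a at 1.86 (SE 0.14) and Sox4 at 1.82 (SE 0.14) beside Dcx and Fabp7. The progenitor list passed camera with adjusted p = 1.23e-04. The list did not pass at adjusted p = 0.308 with an estimated correlation (range 3.66e-05 to 0.308). Of 15 cell cycle genes 8 rose and 0 fell, over all genes and adjusted over the list alone, led by Mcm7 (1.08, SE 0.14), Mcm6 (2.55, SE 0.38), Rrm2 (1.49, SE 0.27) and Top2a (1.04, SE 0.20). The cell cycle list passed camera with adjusted p = 0.00273. It was lost at adjusted p = 0.366 with an estimated correlation (range 8.99e-04 to 0.366), and at adjusted p = 0.228 with the strict filter. Of 15 ribosomal protein genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), led by Rps19 (1.36, SE 0.16) and Rplp0 (0.95, SE 0.11). The ribosomal protein list passed camera with adjusted p = 1.99e-06. The call ended at adjusted p = 0.308 with an estimated correlation (range 3.27e-08 to 0.308). Of 9 interferon response genes 3 rose (4 adjusted over the list alone), Ifit2 (2.17, SE 0.54), Rtp4 (1.93, SE 0.52) and Oasl2 (2.18, SE 0.66). The interferon list passed camera with adjusted p = 0.0193. This call was lost at adjusted p = 0.454 with an estimated correlation (range 4.48e-04 to 0.454), and fry gave adjusted p = 0.0637. This list did not pass without wild-type vehicle replicate 2 (adjusted p = 0.0508) or transplanted replicate 2 (0.109). These rises, too, were measured in arrays with a 25.2-fold lower 18S signal.

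The remaining 24 lists tested did not pass camera in transplanted against wild-type arrays: motor neuron (adjusted p = 0.656), pan-neuronal (0.939; 5 rose and 5 fell of 16, 6 and 7 adjusted over the list alone, with Tubb3 at 1.09 and Vamp1 at -0.98), interneuron (0.802; 2 rose and 3 fell of 14, with Npy at 1.46 and Pvalb at -0.82), oligodendrocyte precursor (0.317; 2 fell of 7), endothelial (0.361; Slco1a4 fell by 0.88). Nor did meningeal fibroblast (0.317; 3 rose of 9, 4 adjusted over the list alone), skeletal muscle (0.699; Pvalb fell), erythroid (0.141; Slc4a1 rose by 1.55 and Alas2 by 1.64), neutrophil (0.837), axon injury (0.0599; 6 rose of 16, 7 with 1 fall adjusted over the list alone, with Gap43 at 2.17 and Ngfr at 2.79), p53 and apoptosis (0.990; 3 rose and 1 fell of 14, 3 and 3 adjusted over the list alone). Others short of the threshold were reactive astrocyte (0.757; 3 rose and 2 fell of 15, with Vim at 1.45), disease-associated microglia (0.317; 1 rose, Igf1, and 5 fell of 14, with Cd9 at -0.93), MHC class I and complement (0.587; 1 rose of 8), neurotrophic factors (0.317; 3 rose and 1 fell of 13), unfolded protein response (0.933; 1 rose and 1 fell of 20), heat shock (0.699; 3 rose and 1 fell of 13, with Hspa1a at 1.4), with no call either for glucocorticoid and fasting (0.170; 2 fell of 15), immediate early genes (0.990; 1 rose of 9), tRNA synthetases (0.656; 3 rose and 1 fell of 22), RNA helicase and survival motor neuron complex (0.228; 2 rose of 11, with Smn1, the gene of the survival motor neuron protein, at 0.71), oxidative phosphorylation (0.154; 1 rose and 3 fell of 30), Hox genes (0.154; 3 rose of 11, with Hoxc8 at 1.25) and aldehyde dehydrogenases (0.0771; 2 fell of 9, with Aldh1a1 at -1.42). Of the list members named against wild type, Isl1, Igf1, Ngfr, Slc4a1, Ifit2, Oasl2, Rtp4 and Mcm6 had mean signals under 51.4 in wild type. Too few genes were measured to test the ependymal (2), Schwann cell (3), dorsal root ganglion (3), adipocyte (3) and lymphocyte (1) lists, in which Sox10, Th, Scd1 and Ighm fell and Isl1 rose. For the motor neuron, pan-neuronal, interneuron, p53, reactive astrocyte and immediate early lists the median, the mean and the direction of camera differed in sign. Each call of a list in the 3 comparisons was lost with an estimated correlation, and the directions of all lists named as past the threshold held under quantile normalization and median centring. The 18S control differed 25.2-fold between the same arrays.

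**Figure D3:**
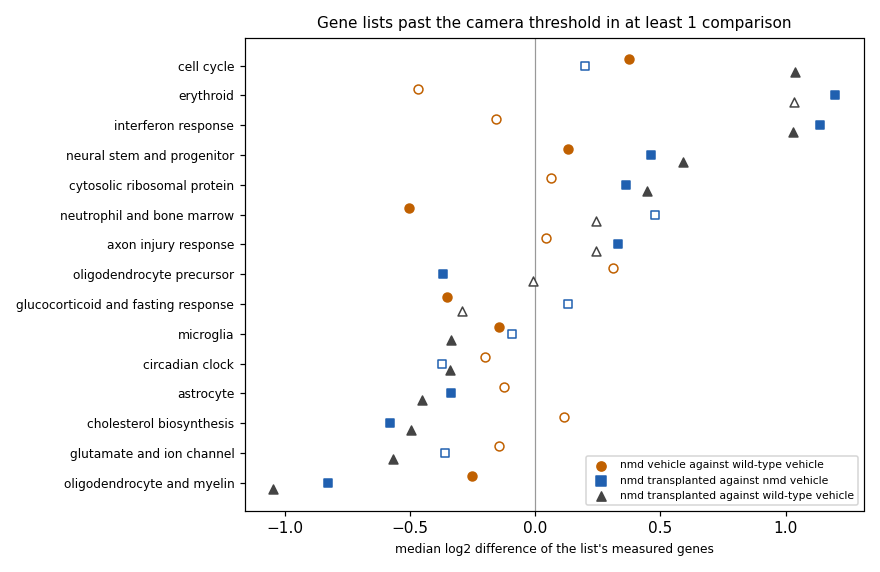
Median log2 difference of each gene list that passed camera in at least 1 of the 3 comparisons. Circles, squares and triangles are the comparisons, and filled symbols passed camera at a preset correlation. The myelin median was -0.25 in nmd against wild-type vehicle, -0.83 in transplanted against nmd vehicle and -1.05 in transplanted against wild-type arrays.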

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

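The tests of dilution, of RNA preparation and of the sex-linked genes were chosen only after the results they bear on were seen. The list of genes that decline after birth was written after some genes of young neurons were seen to be higher, with Igf2 already in the fixed lists. Among control probe sets, which entered no comparison, 9 lay higher in all 3 transplanted arrays than in every wild-type array. These were beta-actin 5' (1.37-fold) and middle (1.34-fold), and spiked bacterial transcripts added before hybridisation: BioB middle (1.78-fold) and, by a further probe set, BioB 5' (1.42-fold), BioC 3' (1.31-fold and 1.36-fold), BioC 5' (1.32-fold and 1.45-fold) and BioD 5' (1.39-fold). With 3 arrays in each group, separation in this direction has a chance of 1 in 20 for any probe set. All 18 probe sets of the BioB, BioC, BioD and Cre spikes averaged higher in the transplanted arrays, by 0.11 to 0.84 on the log2 scale over wild type and by 0.40 to 0.92 over nmd vehicle, with all 3 arrays higher for 7 and for 14 of them. The summary of all 18 was added after these values were seen.

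The progenitor list was higher in transplanted than in nmd vehicle arrays by camera (adjusted p = 8.11e-04, but adjusted p = 0.279 with an estimated correlation), with 5 of 12 genes that rose, Dcx among them, and Prom1 that fell. Young neurons had no list of their own. By camera the progenitor list was also higher in nmd vehicle than in wild type (adjusted p = 0.0397, but adjusted p = 0.543 with an estimated correlation). There only 1 of its 12 measured genes, Fabp7, passed limma's threshold, Cd24a stood at -0.05 on the log2 scale, and St8sia2, in no list, had a signal of 63.9 against 79.7. Less mature tissue may account for part of this. It predicts that genes of an imprinted and growth network that falls after birth are also higher, and they were. By limma's camera this gave adjusted p = 4.36e-04 for transplanted against nmd vehicle and adjusted p = 0.0384 for nmd against wild-type vehicle, with 10 and 9 of 12 measured genes higher. The adjustment, over the 3 comparisons, was added after the unadjusted result was seen and left the outcome of the test as it was. With an estimated correlation the list passed in neither (adjusted p = 0.0822 and adjusted p = 0.223). Not every list of immature cells was higher. By camera the oligodendrocyte precursor list was lower in transplanted than in nmd vehicle arrays (adjusted p = 0.00396, but adjusted p = 0.232 with an estimated correlation). Of its 7 measured genes 4 fell and 0 rose. RNA preparation stays open as well, because the 18S 3' signal was 18.8-fold lower in exactly the transplanted arrays, so that preparation and transplantation cannot be told apart. Expression of these genes by the grafted cells themselves is a further open explanation, not tested here. Grafted cells could also express the list that falls after birth. Its rise in the transplanted arrays therefore cannot tell less mature tissue from grafted cells.

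The myelin, astrocyte and cholesterol lists were lower in transplanted than in nmd vehicle arrays by camera, with 9 of 15, 4 of 12 and 13 of 19 genes that fell. With an estimated correlation these calls were lost (adjusted p = 0.290, adjusted p = 0.405 and adjusted p = 0.232). Dilution of the resident tissue by grafted cells would lower genes of vessels and microglia, which a neural graft does not hold, by about the myelin median of -0.83, which leaves 56.4%. Over 16 bright genes, 5 endothelial and 11 microglial, the mean difference was -0.109 (SE 0.124). This argues against dilution as the whole cause, provided that vessels and microglia did not themselves become more abundant, which was not tested. An earlier form of this test, on abundant myelin genes, was dropped because a high baseline was thought to hide a small change. Its values are not given here, and the predicted -0.83 is not small. The 15 measured myelin genes ran from -1.47 to 0.317. A lower oligodendrocyte and astrocyte content or maturity may remain, and so does RNA preparation, which cannot be told apart from the group.

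Xist was present in 7 of the 9 arrays although all mice are labelled male. Female tissue in some of them may be the cause: over these 7 arrays Xist ran against Uty, the brightest of 3 Y-linked genes (Spearman rho = -0.786, exact permutation p = 0.0480, adjusted 0.0720; Pearson r = -0.922, exact p = 0.00933, adjusted 0.0140). For Eif2s3y rho was -0.893 (exact p = 0.0123, adjusted 0.0369; r = -0.873, exact p = 0.00139, adjusted 0.00417) and for Kdm5d -0.214 (exact p = 0.662, adjusted 0.662; r = -0.674, exact p = 0.116, adjusted 0.116). Without the 2 arrays farthest from the median r was -0.852, -0.802 and -0.363. In the 2 arrays low in Xist, which this test leaves out, Eif2s3y read 55.7 and 70.6, against 2.5 to 33.7 in the other 7. Uty read 50.3 and 49.2 there, under the 61.8 of transplanted replicate 3, and Kdm5d 52.7 and 27.3. Each vehicle group held 1 array low in Xist and the transplanted group 0. The Y-linked genes had mean signals of 35.5, 27.4 and 33.2, all under 51.4, so the sex of the mice was not settled. A first form of the test over all 9 arrays was replaced by this one.

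Other splits of the arrays were counted for each test. Of the 10 splits of 6 arrays into 3 and 3, only the real one gave as many probe sets in each comparison (1 of 10). The counts were 85, 2479 and 3956 against a highest other of 1, 0 and 0, and 10 splits are too few for a share under 0.05. The other splits mix the groups, so that a true difference between groups adds to the spread within them. Their low counts therefore do not show how many calls arise by chance. For any difference among the 3 groups, 1 of 100 splits drawn from 280, the real one, reached 3676 probe sets. The highest other gave 2366, and the median of the others was 0. The share thus lay under 0.05 for that count, although not all 280 splits were run.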

How the results depend on the processing

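The Xist covariate and the fit without both arrays low in Xist were chosen after seeing the data. Ighmbp2 aside, no named gene or list past the threshold turned direction under any alternative run. The shares that follow cover every gene past the threshold that the naming rule selects, not all of which the text prints. Of these, 58 of 102 (transplanted against nmd vehicle), 82 of 113 (transplanted against wild type) and 0 of 20 (nmd against wild-type vehicle) kept their call under all alternatives that gave a value. The strict filter left some genes and lists without a value. The cause of the changes below was not tested.

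For nmd against wild-type vehicle the count of 85 was 15 with no filter, 41 after quantile normalization, 1 with no intensity trend, 371 with array weights, 46 with the Xist covariate, 0 by limma without both arrays low in Xist (1660 unadjusted), and 0 to 254 with single arrays left out. The 6 lists were 2 with the strict filter (0 higher and 2 lower), 0 with an estimated correlation (camera, 2 unadjusted), 3 without both arrays low in Xist and 3 to 7 with single arrays left out. All 6 were lost by fry, which called 1 list that camera had not, oligodendrocyte precursor as higher (fry adjusted p = 0.029). For transplanted against nmd vehicle the count was 1613 without both arrays low in Xist and 1577 to 2511 with single arrays left out, and the 9 lists were 0 with an estimated correlation (camera, 6 unadjusted) and 8 to 11 with single arrays left out. Fry lost the interferon list (adjusted p = 0.0698), and leaving out both arrays low in Xist lost axon injury (0.0743). For transplanted against wild type the count was 3020 to 3824 with single arrays left out, and the 10 lists were 6 with the strict filter, 0 with an estimated correlation (camera, 4 unadjusted), 16 by fry, which lost interferon and microglia of the 10, and 8 to 12 with single arrays left out. These are counts of all lists past the threshold, not only of those called first. The F test gave 2708 to 3556.

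The Ighmbp2 difference between transplanted and nmd vehicle turned to 0.00069 with a pseudocount of 64 and 0.040 with array weights, and ran from -0.145 to 0.066 with single arrays left out. Between nmd and wild-type vehicle it ran from -0.29 to -0.14. The correlation across genes moved to -0.282 with no filter, 0.063 with the strict filter and 0.017 with the pseudocount, and from -0.132 to -0.0100 with single arrays left out. The cross-fitted ratio stayed positive, 0.165 to 0.321. With the replicate number as a block the counts were 76, 2430 and 3926. The numbers did not pair the arrays: 9 same-numbered pairs had correlations of -0.031 to 0.128, 1 of them over 0.1, and 3 of 9 arrays were closest to their own number. Signals under 51.4 limit what dim genes can show.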

Other observations

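The list of genes that decline after birth was written after some genes of young neurons had been seen to be higher in the transplanted arrays. Of its 12 measured genes 7 rose by limma in transplanted against nmd vehicle arrays, among them Dlk1, a growth regulator (1.47 on the log2 scale), Mycn, a transcription factor of dividing progenitors (1.37), Hmga2 (0.92), Mest (0.85) and the imprinted RNA Meg3 (0.73), with Plagl1 (0.34) and Ndn (0.32), genes named after their values were seen. The median was 0.35. Against wild type 8 rose, with a median of 0.62 (camera adjusted p = 9.31e-05 over the 3 comparisons, but adjusted p = 0.0822 with an estimated correlation). Between nmd and wild-type vehicle 0 passed limma's threshold, with a median of 0.15.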
